A study of Solanum lycopersicum with 6 samples.

How the data were processed

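The series holds 6 libraries from tomato leaves: 2 of LTM footprints, 2 of CHX footprints and 2 of mRNA. Per the labels' protocols, plants grew at 28 °C with 12 h of light, and true leaves were collected. The labels disagree on age, with 3 weeks in the tissue field and 2 weeks in the treatment field. For CHX, polysomes were extracted in buffer with 100 µg/ml cycloheximide and digested with RNase, and fragments of 26 to 32 nt were cut from a gel. For LTM, leaves were treated with LTM, the extract received puromycin, and footprints were prepared the same way. Total RNA was taken from an aliquot of the CHX extract and depleted of rRNA. All libraries were sequenced as 75-bp single-end reads.

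The deposited table holds raw counts per gene model and library as whole numbers. Per the file headers, reads were counted over the transcript region for mRNA and over the coding region for LTM and CHX. The aligner, the counting tool, the genome build, the annotation release, any removal of rRNA reads and the treatment of reads with several matches are not given in the sources used here. Counting over different regions adds to the CHX vs mRNA and LTM vs mRNA ratios a part that depends on how much of a transcript is untranslated, and LTM counts over the coding region are not counts at start codons. The lengths of the models were not used here. Reads shared between near-identical models may be split or dropped by the counting, so values of such models are uncertain. In 6 sets of models (12 models with at least 100 counts), all 6 libraries had identical counts within each set.

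Groups and replicate numbers were taken from the sample titles. Analysis used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Models were kept by edgeR's filterByExpr with the 3 kinds of library as groups, which kept 20806 of 35768 models and at least 99.95% of each library's counts. Libraries were scaled by TMM factors, which ran from 0.863 to 1.16. One quasi-likelihood model (glmQLFit, glmQLFTest) was fitted to all 6 libraries with the kind of library as the factor, leaving 3 residual degrees of freedom. With 1 biological condition there is no interaction, so each ratio is a contrast of 2 kinds in this model. The 3 contrasts were CHX vs mRNA, LTM vs CHX and LTM vs mRNA, each two-sided, with Benjamini-Hochberg adjustment over all models kept and a threshold of 0.05. TMM assumes that most models do not differ, so "higher" and "lower" are relative to the bulk of the models, and no absolute change in ribosome loading can be read from these counts. Levels are CPM with TMM factors, and log2 CPM used a prior count of 2. The filter of 10 CPM and the count of models seen in one kind of library alone used CPM on library totals. Fitted fold changes used the default prior count of edgeR's fit instead. Values are given as mean ± SD of 2 libraries. The common dispersion of 0.0306 corresponds to a biological coefficient of variation of 0.175 between replicates, and the median SE of a log2 fold change was 0.22 in CHX vs mRNA and in LTM vs CHX and 0.23 in LTM vs mRNA.

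Depth ran from 18240140 counts (LTM replicate 1) to 48704200 (CHX replicate 1). A count of 0 allows up to 3 counts, which with the TMM factors is 0.141 CPM in the shallowest library and 0.0684 CPM in the deepest. A fold against a kind of library at 0 counts was computed against 3 counts over its 2 replicates, and one against 1 to 3 counts is given with an exact binomial interval. Reads carry no molecular identifiers as far as the labels say, so intervals and limits cover counting error only. The procedure was tested on simulated counts drawn from the means and library sizes of these libraries, with 100 models changed 2-fold and 100 changed 4-fold, all with a mean of at least 50 counts. Recovery of scarcer models was not tested. In CHX vs mRNA (20427 models) it recovered 41% of the 2-fold and 100% of the 4-fold changes, and 8.44% of its calls were false. In LTM vs CHX (20550 models) it recovered 43% and 100%, with 13.9% of calls false, and in LTM vs mRNA (20483 models) 52% and 98%, with 10.7% false. The share of false calls in these simulations lay above the 5% that the threshold aims at, where few models were changed.

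Tests, alternatives and the rule for named models were fixed before the data were examined. The rule takes, per comparison and direction, the 2 models with the largest fitted fold change among those with adjusted p under 0.05, a mean of at least 10 CPM over the 6 libraries, and both libraries of one kind above both of the other. It was written to name 8 described genes per direction, members of gene lists and the 10 most abundant genes of each kind where names are given. The deposited table does not pair its identifiers with names, and 0 entries of the tomato gene table at hand (assembly SLM_r2.1) carry such an identifier. Naming was therefore held to 2 identifiers per direction, the most abundant models are described without identifiers, and the tests of 23 fixed gene lists and the 2 planned relations to coding length and to upstream start codons were not run. The filter keeps a model under 0.1 CPM of mRNA only where it has enough footprints, so that class is not chosen independently of the ratios. Classes of level, the limits for models at 0 counts and the repetition of the level classes and of the counts of 8-fold changes under other settings were chosen after the data were seen. The alternatives were DESeq2 size factors, upper-quartile factors, total counts, no filter, a filter of 10 CPM in 2 libraries, the DESeq2 test, limma voom, fits to the 4 libraries compared, the replicate number as a block, a 2-fold minimum, leaving out the models that ranked in the top 20 of any kind (38), and leaving out each library in turn. Fits with 1 library of a kind assume that it varies like the other kinds.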

Results

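Leaves of tomato (Solanum lycopersicum) were profiled in 6 libraries of 3 kinds, with 2 replicates of each kind. Ribosome profiling sequences the short pieces of mRNA that a ribosome shields from RNase, called footprints. The CHX libraries hold footprints from extracts made with cycloheximide, an inhibitor that arrests ribosomes during elongation, and the labels give them as elongating ribosomes. The LTM libraries hold footprints from LTM-treated leaves, whose extracts also received puromycin, and the labels give them as initiating ribosomes without spelling out the abbreviation. The mRNA libraries hold rRNA-depleted total RNA from aliquots of the CHX extract, and mRNA of the LTM-treated leaves was not analysed here. The series set out to find where translation starts in tomato leaf and to measure mRNA abundance. The counts used here cover whole gene models, so positions within a gene were not analysed here. Footprints were counted over the coding region and mRNA over the whole transcript region, so a ratio between them also depends on the share of a transcript that is untranslated.

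Total counts were 24810169 and 30371574 in mRNA replicates 1 and 2, 48704200 and 47856048 in the CHX replicates, and 18240140 and 38983295 in the LTM replicates. Of 35768 gene models, 8175 had no count in any library, and 20806 had enough counts to be tested. A few models took a large part of the mRNA libraries: the 20 most abundant models held 40.9% and 33.7% of the counts there, against 24.8% and 24.4% in CHX and 21.4% and 22.6% in LTM. The most abundant model of the mRNA libraries took 9.06% ± 2.59 of their counts (SD, n = 2), and 0.146% ± 0.00514 of CHX and 0.171% ± 0.0270 of LTM counts. Another model led both kinds of footprint library, with 4.65% ± 0.0915 of CHX and 4.02% ± 0.126 of LTM counts, against 2.87% ± 0.0756 of mRNA counts. Of the 10 most abundant models of each kind, CHX and LTM shared 7, and mRNA shared 4 with either.

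Replicates of one kind were closer to each other than to the other kinds. Across gene models, which are not independent replicates, Pearson's r of log2 CPM between replicates was 0.985 in mRNA, 0.986 in CHX and 0.978 in LTM. Between the group means it was 0.886 for CHX and LTM, 0.855 for mRNA and CHX, and 0.755 for mRNA and LTM. The replicate pairs differed by more than the sampling noise expected of repeated sequencing of a single library, with chi-square values per degree of freedom of 52.8 in mRNA, 47.1 in CHX and 48.3 in LTM. This does not show where the difference arose, and the labels do not say whether the replicates came from separate plants, so p-values measure only the spread between these libraries, which may be technical.

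The comparison of CHX with mRNA asks how many elongating ribosomes a gene model carried for its amount of mRNA, a ratio known as translational efficiency. The mRNA libraries are rRNA-depleted total RNA and can hold RNA other than mRNA, so a low ratio need not mean poor translation. Footprints were low relative to mRNA in 5708 models (27.4%) and high in 4680 (22.5%), in edgeR's quasi-likelihood test with Benjamini-Hochberg adjusted p under 0.05. The low side reached further, with 1343 models at least 8-fold lower in the fit and 308 at least 8-fold higher. With models at 0 counts in one kind of library placed at the limit that 3 counts over its replicates allow, these numbers were 1330 and 261, and in a fit to the 8292 models of at least 10 CPM in 2 libraries they were 368 and 39. From 1 CPM of mRNA upward, the footprints carried per mRNA rose with the mRNA level. That level is in CPM, which is not divided by transcript length and so mixes abundance with length. The median log2 ratio was -0.19 in the 9593 models from 1 to 10 CPM of mRNA, 0.15 in the 5842 from 10 to 100 CPM and 0.52 in the 887 at 100 CPM or more, although classing by the mRNA in the denominator works against such a rise. Of the 887 models with most mRNA, 50.7% were higher in CHX and 24.8% lower. Below 1 CPM of mRNA the medians depended on the filter. Among models with more than 3 counts in these 2 kinds of library, they were -0.16 in the 3837 tested from 0.1 to 1 CPM and 2.996 in the 537 under 0.1 CPM, which could pass only through their footprints. With no filter they were -0.51 in 5371 and 0.98 in 2464 such models. With summed counts of a kind under 3 set to 3, the medians under 0.1 CPM were 2.03 with the filter and 0.22 without it. The rise above 1 CPM was present with DESeq2, upper-quartile and total-count scaling, with no filter, and without any single library. The fit to models of at least 10 CPM, which selects scarce transcripts by their footprints, gave 0.21, -0.09 and 0.25 in these 3 classes and 31.6% of the highest class higher. Without mRNA replicate 1, 29.8% of that class were higher. The number of models higher in CHX fell to 2676 without mRNA replicate 1 and to 2914 without mRNA replicate 2.

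The identifiers in the table come without gene names, so models are given by identifier, and only 2 in each direction. Solyc06g016695.1.1 had 1059 and 967 CPM in the mRNA replicates (mean 1013 ± 65.1, SD, n = 2) and 0 counts in all CHX and LTM libraries, which puts it at least 30395-fold lower in CHX (edgeR adjusted p = 4.22e-06). Solyc08g023497.1.1 had 369 and 955 CPM in mRNA and 0 footprint counts, at least 19860-fold lower in CHX by the mean and at least 11062-fold by mRNA replicate 1 alone (edgeR adjusted p = 0.000133). In the other direction, Solyc10g054350.1.1 had 33.4 ± 3.90 CPM in CHX and 0 counts in mRNA, at least 586-fold higher (edgeR adjusted p = 4.22e-06). It also had 15.1 and 16.9 CPM in the LTM replicates. Solyc03g117830.1.1 had 0 counts in mRNA and differed widely between the CHX replicates, at 4.74 and 321 CPM. Its mean was at least 2854-fold higher in CHX, but CHX replicate 1 alone was at least 83.1-fold higher. The edgeR adjusted p was 0.0476, and it was 0.214 without CHX replicate 2, 0.122 without mRNA replicate 1 and 0.147 without mRNA replicate 2, and ran from 3.39e-05 to 0.451 over all settings. These limits take 3 counts over both libraries of the kind at 0 and cover counting error only. They also set the transcript region in rRNA-depleted total RNA against the coding region in footprints. Whether the mRNA reads of the models with 0 footprint counts lay in a coding region was not analysed here.

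**Figure D1:**
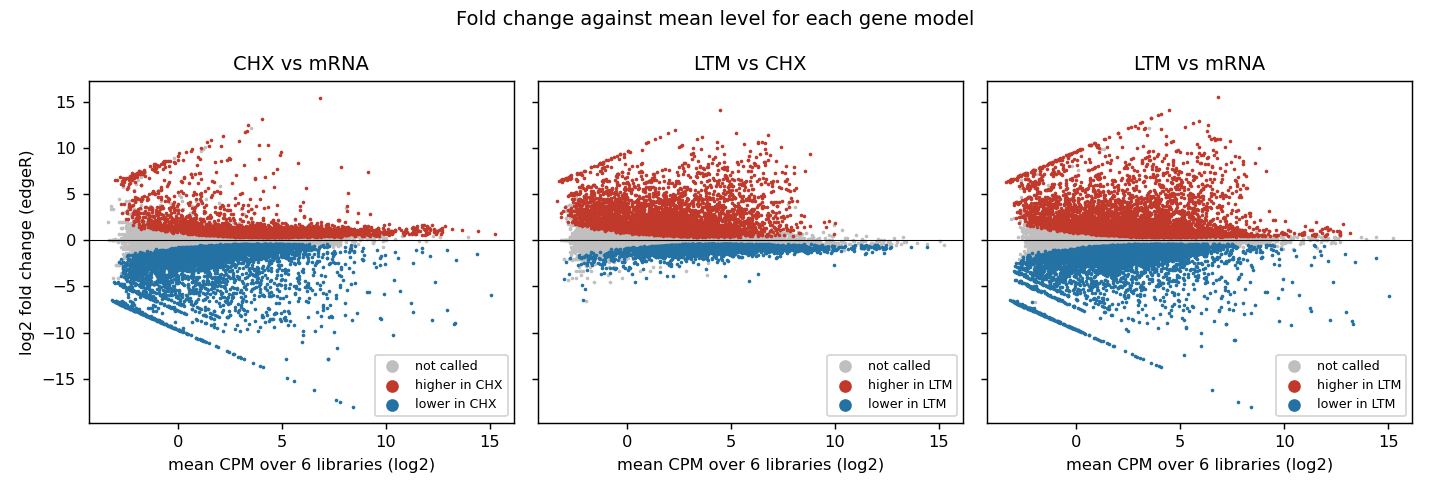
Log2 fold change fitted by edgeR (y) against the mean level in log2 CPM over the 6 libraries (x) for each of the 20806 models tested, in the 3 comparisons. Each point is a gene model, red where it was higher and blue where it was lower in the first-named kind of library at an adjusted p under 0.05, and grey where it was not called. The straight edges of points are models with 0 counts in one kind of library, whose fitted fold change depends on the default prior count of edgeR's fit. Large changes were mostly downward for CHX vs mRNA and mostly upward for LTM vs CHX.

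The comparison of LTM with CHX sets footprints of initiating ribosomes against those of elongating ribosomes in each gene model. LTM footprints were higher in 4654 models (22.4%) and lower in 4074 (19.6%) in edgeR's test. The changes were uneven in size: 1283 models were at least 8-fold higher in LTM in the fit and 27 at least 8-fold lower, or 1256 and 23 with models at 0 counts placed at their limit. Without LTM replicate 2 these numbers were 1245 and 74 in the fit, without CHX replicate 2 they were 1391 and 17, with total counts 1490 and 15, and with the 10 CPM filter 600 and 3. The ratio fell as the mRNA level rose, although only 1558 (33.5%) of the models higher in LTM had under 1 CPM of mRNA. The median log2 ratio was 0.62 in the 3837 models from 0.1 to 1 CPM of mRNA, 0.06 in the 9593 from 1 to 10 CPM, -0.32 in the 5842 from 10 to 100 CPM and -0.42 in the 887 at 100 CPM or more. The mRNA came from aliquots of the CHX extract, so these classes are not independent of the CHX counts in the ratio. CPM is also not divided by transcript length, so the classes mix abundance with length. A single start site weighs more in a short coding region, and whether length gave part of the fall was not tested. Classed by LTM level over the same ranges, which works against a fall, the medians were flatter, at 0.22, 0.02, -0.17 and -0.23. Under 0.1 CPM of LTM the median was -0.24. Models under 0.1 CPM of mRNA could enter the test only through their footprints, so their median depends on the filter: it was 2.11 in the 647 tested (interquartile range -0.25 to 5.35), and 0.65 in the 2925 with more than 3 footprint counts when no filter was applied, or 0.48 with summed counts of a kind under 3 set to 3. The share of models called higher was 31.5% from 0.1 to 1 CPM of mRNA and 7.78% in the class with most (12.4% without LTM replicate 1), where 41.1% were called lower.

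From 0.1 CPM of mRNA upward the order of these medians was the same under every scaling and filter tried and without any single library, whereas their size and the level called unchanged were not. With the 10 CPM filter, which keeps scarce transcripts only where footprints are many, the medians were 6.16 from 0.1 to 1 CPM and 0.95 from 1 to 10 CPM of mRNA, and 8.29 in the 61 models left under 0.1 CPM. That lowest class had a median of 1.71 without LTM replicate 2 and 2.83 without CHX replicate 2. Scaling to total counts moved the ratios of the models by a median of 0.29 on the log2 scale relative to edgeR's TMM factors. It gave 5812 models higher and only 1228 lower, so that 82.6% of the calls were upward against 53.3% with TMM. In the class with most mRNA it gave 14.0% higher and 12.5% lower, with a median of -0.13. The number of models lower in LTM was 2482 without CHX replicate 1, and 23.7% of the class with most mRNA were then lower.

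**Figure D2:**
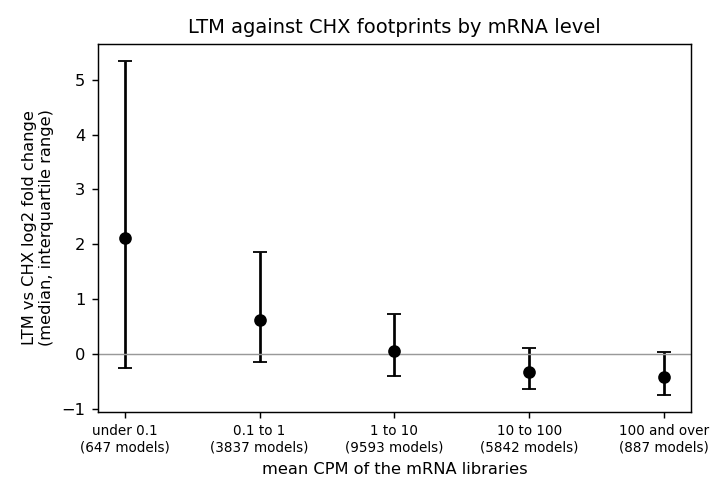
Median (points) and interquartile range (bars) of the log2 fold change of LTM vs CHX (y) in gene models grouped by their mean CPM in the 2 mRNA libraries (x). The number of models is given under each class. CPM is not divided by transcript length. The median falls from 0.62 at 0.1 to 1 CPM to -0.42 at 100 CPM or more, and the lowest class, with a median of 2.11, holds only models that passed the filter through their footprints.

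Solyc06g035700.1.1 had 65.4 ± 4.78 CPM in LTM (SD, n = 2) and 0 counts in both CHX and both mRNA libraries, which makes it at least 1963-fold higher in LTM than in CHX (edgeR adjusted p = 3.46e-06). Solyc01g090310.2.1 had 114 ± 9.32 CPM in LTM and 3 counts in CHX, all in replicate 2, a ratio of 3478 with a 95% exact binomial interval of 1190 to 16867 (edgeR adjusted p = 1.58e-06). Against CHX replicate 2 alone the ratio was 1783 (610 to 8649), and against CHX replicate 1 alone it was at least 1661. The fitted log2 fold change of 11.59 was 10.69 without CHX replicate 1, and 14.84 without CHX replicate 2, where it depends on the prior count of the fit. Solyc08g023660.3.1 was lower in LTM, at 5.38 ± 3.35 CPM against 120 ± 0.859 in CHX, a log2 fold change of -4.44 (SE 0.39, edgeR adjusted p = 8.54e-05). That value was -5.31 without LTM replicate 2 and -3.95 without LTM replicate 1. Solyc04g007010.3.1 was also lower, at 3.23 ± 2.91 CPM in LTM against 51.9 ± 14.5 in CHX, a log2 fold change of -3.92 (SE 0.55, edgeR adjusted p = 0.00108). It was -5.46 without LTM replicate 2 and -3.30 without LTM replicate 1. The mRNA of Solyc08g023660.3.1 was at 50.2 and 52.3 CPM, and that of Solyc04g007010.3.1 at 20.1 and 26.1 CPM.

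The comparison of LTM with mRNA sets initiating-ribosome footprints against transcript level, with the 2 kinds of library taken from differently treated leaves. LTM was higher in 5299 models (25.5%) and lower in 5691 (27.4%) in edgeR's test. Large changes went both ways, with 1306 models at least 8-fold higher and 1080 at least 8-fold lower in the fit, 1244 and 1074 with models at 0 counts at their limit, and 577 and 319 with the 10 CPM filter. By mean level over the 6 libraries, which include those compared, the median log2 ratio was 0.07 under 1 CPM, -0.07 at 1 to 10 CPM, 0.06 at 10 to 100 CPM and 0.20 at 100 CPM or more. Upper-quartile factors turned the first and the third of these medians to -0.01. The 10 CPM filter turned the second to 0.33 and the third to -0.01. Total counts moved the models up by a median of 0.27, with 62.2% of calls upward against 48.2%. Without LTM replicate 2 the first median was -0.08.

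The models that stood out against mRNA were largely those named above. Solyc06g035700.1.1 was at least 1146-fold higher in LTM than in mRNA (edgeR adjusted p = 3.43e-06). Solyc03g117830.1.1 had 0.471 and 356 CPM in the LTM replicates, a mean at least 3123-fold above mRNA with an edgeR adjusted p of 0.0438, while LTM replicate 1 alone was at least 8.26-fold above it. That adjusted p was 0.570 without LTM replicate 2, 0.113 without mRNA replicate 1 and 0.134 without mRNA replicate 2, and ran from 2.39e-05 to 0.570 over all settings. Solyc06g016695.1.1 was at least 21853-fold lower in LTM than in mRNA (edgeR adjusted p = 1.84e-06), and Solyc08g023497.1.1 at least 14279-fold lower by the mean and at least 7954-fold by mRNA replicate 1 alone (edgeR adjusted p = 6.11e-05).

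**Figure D3:**
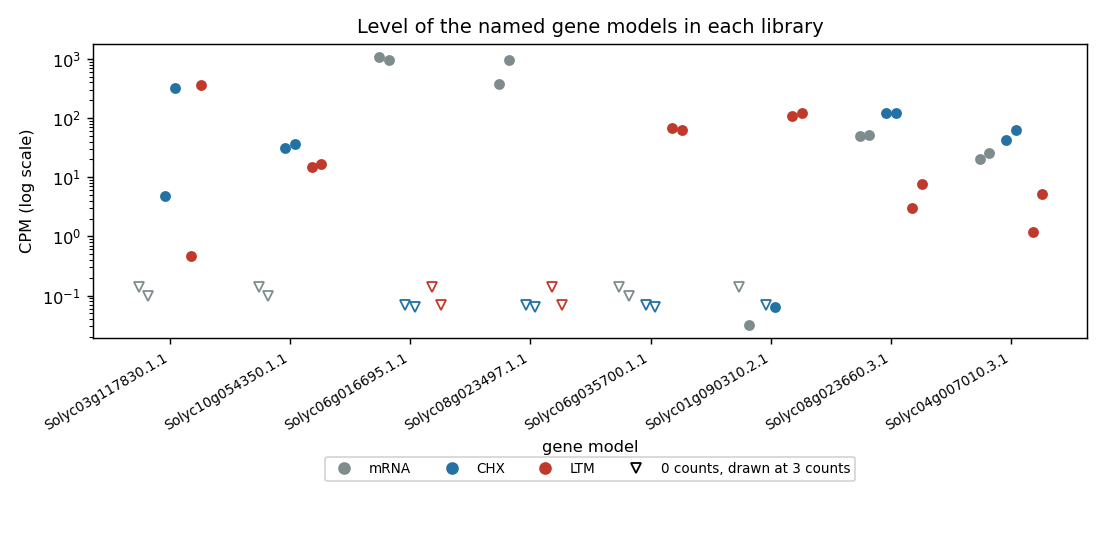
Level in CPM on a log axis (y) of the 8 named gene models (x) in each library, with mRNA in grey, CHX in blue and LTM in red. Each filled circle is 1 library, and open triangles mark libraries with 0 counts, drawn at the level of 3 counts. The 2 models with counts in the mRNA libraries alone, Solyc06g016695.1.1 and Solyc08g023497.1.1, have no coding-region footprint count in any of the 4 libraries. The 2 replicates of Solyc03g117830.1.1 lie far apart in both CHX and LTM.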

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

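Leaving out models with discordant replicates and keeping identical models once were settings chosen after the data were seen. No call reversed in any setting, and 102 of the 114 alternative counts of called models were within 1.5 times the reported ones. With at least 10 CPM required, 8292 models were tested, and the counts higher and lower were 1700 and 2334 for CHX vs mRNA, 2222 and 1717 for LTM vs CHX, and 2454 and 2292 for LTM vs mRNA. The lower counts follow in part from fewer models tested. This filter moved the log2 ratios of the models kept, by a median of -0.27 for CHX vs mRNA and 0.20 for LTM vs CHX. A 2-fold minimum left 1741 models higher in CHX than in mRNA and 1022 lower in LTM than in CHX. Total counts in place of TMM gave 1228 models lower in LTM than in CHX, after a shift of the models by a median of 0.29. Leaving out 1 library gave 2676 (without mRNA replicate 1) to 4920 models higher in CHX than in mRNA, with 2914 without mRNA replicate 2, and 4055 to 6007 lower. It gave 3585 to 4512 models higher and 2482 (without CHX replicate 1) to 3520 lower in LTM than in CHX, and 3725 to 5220 higher and 4039 to 5724 lower in LTM than in mRNA. Fewer libraries leave fewer degrees of freedom, and beyond that the cause was not tested. The 1283 models at least 8-fold higher in LTM than in CHX numbered 600 under the 10 CPM filter and 1230 to 1490 in the other settings. The labels do not say that a replicate number marks one extract or batch, although the mRNA came from aliquots of CHX extracts, so libraries of different kinds were not treated as paired. Deviations from the group means correlated at 0.356 for mRNA and CHX, 0.338 for CHX and LTM and 0.207 for mRNA and LTM, and a replicate block gave 5623 and 6326 calls for CHX vs mRNA, 5330 and 5297 for LTM vs CHX, and 6062 and 6313 for LTM vs mRNA. Of 214 alternative values for the named models, 203 kept direction and call, and the 11 that missed the threshold all belong to Solyc03g117830.1.1. Not run, for want of gene names, coding lengths and 5' UTRs in the tables used here, were the 23 gene lists, both planned relations to sequence features, and the removal of organelle-encoded genes. Depth leaves only a limit for ratios of models at 0 counts, of which the tested models held 333 in CHX, 220 in mRNA and 193 in LTM.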

Other observations

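Some models appeared in one kind of library alone. CPM here was taken on library totals, without TMM factors. With at least 10 CPM in both libraries of one kind and at most 3 counts in each of the other 4, 21 models were seen in mRNA alone. By the same rule 15 were seen in LTM alone and 0 in CHX alone, while 4837 models reached 10 CPM in all 6 libraries. Solyc06g016695.1.1 and Solyc08g023497.1.1 are among the first set and Solyc06g035700.1.1 and Solyc01g090310.2.1 among the second. Models with identifiers that open with Solyc00 were also counted apart. Of the 194 tested, 85 (43.8%) were lower in CHX than in mRNA in edgeR's test, against 27.3% of the 20612 others, and 92 (47.4%) were lower in LTM than in mRNA, against 27.2%. Between LTM and CHX, 44 of them (22.7%) were higher, against 22.4% of the others, and 26 (13.4%) were lower, against 19.6%. With total counts the shares lower were 4.64% against 5.91%. The median LTM vs CHX log2 ratio was 0.23 in these models against -0.02 in the others. It was 0.27 against -0.03 without LTM replicate 1 and 0.39 against -0.002 without CHX replicate 2. The gap was smaller without CHX replicate 1, at 0.07 against -0.01, and without LTM replicate 2, at 0 against -0.04. With the 10 CPM filter 35.5% against 26.7% were higher. The difference between these shares was not tested, since models are not independent replicates.

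Of the tests below, the one of stalling in members with enough mRNA to show it and those of other transcript levels, of short coding regions, of differing plants and of fragments other than mRNA were chosen only after the results they measure had been seen.

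The first pattern is the set of 1283 models at least 8-fold higher in LTM than in CHX, of which 796 (62.0%) had under 1 CPM of mRNA in both libraries, although 684 (53.3%) had at least 100 counts in both LTM libraries. If ribosomes were stalled at the start of transcripts that are rarely elongated, CHX footprints should be scarce for the mRNA present, but the median CHX vs mRNA log2 ratio of the set was -0.32 (bootstrap interval -0.45 to -0.18, and -0.41 with models at 0 counts at their limit), although choosing models with few CHX footprints pulls this value down. Members with too little mRNA cannot show a deficit, and 224 had at most 3 mRNA counts in total. In the 959 with enough mRNA for 3 CHX counts to show a log2 ratio of -2, the median was -0.69 (bootstrap interval -0.86 to -0.50). The bootstraps resampled models, which are not independent, so their intervals leave out the spread between libraries. The median of -0.69 argues against stalling that lowers the ratio to -2 or below in all of these 959. The mark of -2 was a choice, and the ratio is relative to the bulk of the models. Stalling with a weaker deficit stays open. It also stays open for members with too little mRNA and for part of the set. Of the set, 310 members (24.2%) lay at -2 or below. That share was 10.3% among all models tested, and models matched on LTM footprints had a median of 0.13. Choosing models with few CHX footprints lowers the ratio by itself, so neither gap counts in favour of stalling. The set was also high in LTM for its mRNA, with a median LTM vs mRNA log2 ratio of 3.95 (3.78 with models at 0 counts at their limit). Choosing models with many LTM footprints raises that value by itself. Transcript levels that differed in the LTM-treated leaves stay open: the median mRNA level was 0.495 CPM against 6.79 CPM in models matched on LTM footprints, a ratio of 0.0729, but a low ratio follows from choosing models with few CHX footprints, and mRNA of LTM-treated leaves, which would decide it, was not analysed here. Short coding regions, where a single start site weighs more, cannot be told apart from this without coding lengths, and 325 of the models were at least 64-fold higher in the fit (256 with models at 0 counts at their limit).

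The second pattern is a set of 26 models, Solyc03g117830.1.1 among them, that differed over 8-fold between the replicates in both CHX and LTM in the same direction, where 0.0922 would be expected if the 44 such models in CHX and the 57 in LTM were unrelated; 24 of the 26 were higher in replicate 2 of both. Plants that differed between the replicates would show the same gap in mRNA, where the median log2 difference was 0.955, less than such a gap needs but above 0, and 1.46 in the 11 members with at least 1 CPM of mRNA, so this stays open. Fragments of RNA other than mRNA stay open too: 57.7% of the set had under 1 CPM in both mRNA libraries against 19.8% of all models tested. This share cannot decide it, since scarce transcripts also have little mRNA. The mRNA libraries, as rRNA-depleted total RNA, can hold RNA other than mRNA as well. Leaving out all 86 models that differed over 8-fold between the replicates of any kind gave 4756 models higher and 4202 lower in LTM than in CHX.

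The third pattern is the placing of the models at least 8-fold higher in LTM than in CHX along the order of the identifiers. Only tested models were placed, and those with identifiers that open with Solyc00 were left out of every set. This left 1274 members. Members stood next to each other in 209 pairs. In 10000 random draws the median was 79 and the maximum 112 (permutation p = 0.0001, the smallest that these draws can give). With draws within classes of mean level the maximum was 115. This argues against random placing of single models, but the draws were not matched on mRNA level. Other sets were grouped too, with 105 pairs against 49 for models at least 2-fold lower in LTM than in CHX and 293 against 79 for models at least 8-fold lower in CHX than in mRNA, so grouping is not special to LTM. The last of these sets overlaps the first pattern, as 206 of its 1283 models were at least 8-fold lower in CHX than in mRNA. Neighbouring copies that share reads or are regulated together could both give this, and neither was tested.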
